A study of Mus musculus with 22 samples.

How the data were processed

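RNA sequencing libraries from mouse brain tissue were analysed from gene-level values as the authors deposited them. The 22 libraries come from 2 regions, the vestibular nuclei (VN) and the spinal trigeminal nucleus caudalis (Sp5C), and from 3 treatments. Vehicle (VEH) and nitroglycerin (NTG) have 4 libraries per region, and nitroglycerin with kainic acid (NTGKA) has 3. Per the labels' protocols, RNA was extracted with a column kit, 1.3 µg of total RNA went into each library, and libraries were made with a SMARTER mRNA kit. The builds GRCm38 and mm10, which name the same mouse assembly, are listed in the submitters' processing notes. The aligner, the counting program, the annotation and the use of strand in counting are not given in the sources used here.

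The authors deposited whole-number read counts per gene and FPKM values (fragments per kilobase of gene, scaled by library) for every library, per the file headers. Columns of fold changes and p-values for the authors' own comparisons stand in the same deposited table under group letters that the labels do not define, and were not used here. The table has 16383 lines below its header, of which 8 are overflow of long text. The other 16375 are genes, and 1181 of these have 0 counts in all libraries. The table was held only in part: its gene identifiers stop early, where the reference annotation has 16999 of its 55450 genes up to the last identifier listed. Genes beyond that point are not analysed here, and totals of counts are over the listed genes only. They ranged from 23.9 to 39.4 M per library, with group means and SD of 27.5 ± 0.563 (VN VEH, n = 4), 25.9 ± 1.65 (VN NTG, n = 4), 31.2 ± 7.17 (VN NTGKA, n = 3), 28.2 ± 1.38 (Sp5C VEH, n = 4), 25.1 ± 1.35 (Sp5C NTG, n = 4) and 27.3 ± 1.45 M (Sp5C NTGKA, n = 3).

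Libraries were grouped by title, tissue and treatment label. A further label field names the other region for each of the 22 libraries, so the region was checked with Hox genes, which are expressed in the caudal hindbrain and spinal cord. The labels do not say that replicates came from separate animals or that the regions came from the same animals, so p-values measure the spread between these samples, which may be technical. No library was a repeat of another.

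Counts were tested with edgeR (4.0.16, in R 4.3.3): the quasi-likelihood test, TMM factors, its default low-count filter, and Benjamini-Hochberg adjustment over all genes tested with a threshold of 0.05. P-values are two-sided, except permutation p-values of shares of genes and where one-sided is stated. Each region was fitted on its own over 11 libraries (13356 genes for Sp5C, 13342 for VN). The comparison of regions and the differences between regions in treatment response were fitted over all 22 libraries (13650 genes). The design had been written for FPKM, with edgeR to be used if counts were present, and counts were present. Fold changes are edgeR's log2 values with standard errors (SE); FPKM values are means with SD. The comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined. Named genes were Trpv2, the 8 largest rises and falls among genes past the threshold with a mean FPKM of 1 or more in a group, up to 8 ion channels with the smallest p, and up to 4 members with the smallest p of each list described. Some genes that this rule names are not reported here. Where fewer than 10 genes passed, the 5 genes with the smallest p in each direction and 3 channels were taken. Trpv2 was also tested with an exact permutation test of log2(FPKM + 0.5). A list of ion channels and further gene lists, 47 in all, were tested with camera in limma (3.58.1) with a preset correlation between genes of 0.01, and again with an estimated correlation.

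Tests were checked on simulated counts with 200 changed genes in each of 5 runs. For VN NTG against VEH, 13342 genes, edgeR recovered 50.1% of genes changed 1.5-fold, 75.8% changed 2-fold and 89.7% changed 4-fold. For Sp5C NTG against VEH, 13356 genes, the shares were 39.7%, 74.0% and 91.5%. False calls made up 5.03% and 5.27% of the calls. The simulated genes varied independently of each other, without spread that many genes share within a library. These rates may therefore not hold for the real libraries. Alternatives were other pseudocounts with limma on FPKM, other filters and scalings, a replicate block, sample weights, DESeq2 (1.42.0), other sets of libraries in the fit and leaving out each library. A fold change against a group with 0 counts is given as a bound from 3 counts over the group, which covers counting error only. The interval for Pax7 is from counts summed over libraries and leaves out the spread between them.

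Without the use of strand, reads of a gene and of an overlapping antisense gene cannot be told apart. Exons of the following named genes overlap another annotated gene (GENCODE, GRCm38), and their values are uncertain: Plin4, Pax8, Hoxb3, Hoxa4, Hoxb5, Kcnab3, Atp6v1g2, Bhlhe40, Crtac1, Cyren, Dlg2, Dnah1, Enpp2, Gabra5, Gata3, Gbx2, Gm49322, Hopx, Hoxa2, Hoxc5, Itpr1, Kcnab2, Kcnj3, Kcnn2, Myoc, Nanp, Orai1, Osgepl1, Pcif1, Pde3a, Rgs12, Rimbp2, Ripk1, Rpl10a, Shank1, Sprn, Stac, Ttyh1 and Vat1. Rps27rt, a retrogene copy of a ribosomal protein gene, is uncertain because its reads may come from its parent gene.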

Results

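Gene expression was measured in the vestibular nuclei, which receive input from the balance organs, and in the spinal trigeminal nucleus caudalis, which relays pain from the head. Mice received vehicle, nitroglycerin (10 mg/kg, intraperitoneal, 5 injections over 9 days), a donor of nitric oxide that is used to model migraine, or the same nitroglycerin with kainic acid, an agonist of glutamate receptors, applied at the tympanic membrane (0.10 ml of a 12.5 mM solution). Each region had 4 VEH, 4 NTG and 3 NTGKA libraries, with 23.9 to 39.4 M counts per library over the listed genes. The study's title names the channel Trpv2, and its stated aim was to find ion channels that differ.

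Trpv2 (ENSMUSG00000018507), a calcium-permeable cation channel, was highest in the vehicle VN. The gene lies on chromosome 11 of GRCm38 from 62574486 to 62600515 on the plus strand, is protein coding and overlaps no exon of another gene. Its level in the VN was 6.62 ± 1.15 FPKM in VEH (SD, n = 4), 4.13 ± 1.22 in NTG (n = 4) and 3.82 ± 0.0914 in NTGKA (n = 3). In the Sp5C it was 3.10 ± 0.636 in VEH (n = 4), 2.89 ± 0.827 in NTG (n = 4) and 3.44 ± 0.208 in NTGKA (n = 3). Trpv2 fell in the VN with NTGKA, with a log2 fold change of -0.77 ± 0.18 (SE, edgeR adjusted p = 0.0369), and all 3 NTGKA libraries were below all 4 VEH libraries (exact permutation p = 0.0286). With NTG alone the change was -0.61 ± 0.16, which did not pass over all genes (edgeR adjusted p = 0.0830, exact permutation p = 0.0571) and did when adjusted over the list alone (edgeR adjusted p = 0.0214). In the Sp5C the changes were -0.07 ± 0.19 for NTG (edgeR adjusted p = 0.997, exact permutation p = 0.571) and 0.07 ± 0.20 for NTGKA (exact permutation p = 0.371). The NTGKA call in the VN was lost without VEH 1 (-0.75), VEH 3 (-0.69), VEH 4 (-0.78), NTGKA 1 (-0.79), NTGKA 2 (-0.72) or NTGKA 3 (-0.79), and with limma on FPKM under quantile normalization (-0.62), median scaling (-0.66) or a pseudocount of 0.1 (-0.76). The NTG change passed without NTG 3 (-0.78) or VEH 2 (-0.68). Trpv2 in the VN also followed a score of cholinergic and monoaminergic neuron markers inside the groups (r = 0.845, rho = 0.618, 11 libraries). The r was 0.460 without NTG 1 and NTG 3, the 2 libraries whose score lay farthest out once group means were taken off. Those means still included both libraries.

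**Figure D1:**
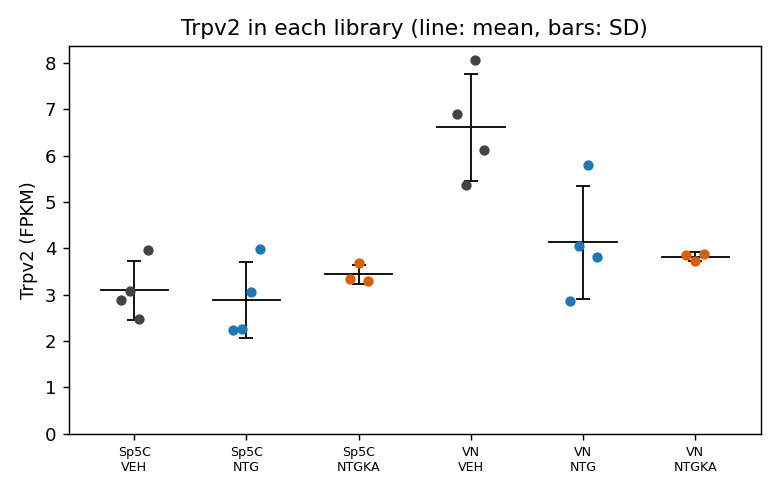
Trpv2 level (FPKM, vertical axis) in each of the 22 libraries by region and treatment; points are libraries, horizontal lines are group means and bars are SD. The 4 vehicle VN libraries range from 5.37 to 8.07 FPKM, and the 3 VN NTGKA libraries from 3.72 to 3.88.

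In the VN, NTG against VEH asked what repeated nitroglycerin changes. The transcription factor genes Hoxb3 (1.92 ± 0.42), Pax8 (1.75 ± 0.37) and Pax2 (1.43 ± 0.30), which specifies inhibitory interneurons, rose. Plin4, a lipid droplet coat protein, rose by 1.84 ± 0.40, and Lamp5, a lysosome-associated protein of some inhibitory neurons, by 1.30 ± 0.28 (61.7 ± 26.1 FPKM in VEH, 146 ± 51.0 in NTG, SD, n = 4 each). Inhba, Kirrel2 and the neuronal transcription factor Neurod2 rose by 1.13 ± 0.21, 1.10 ± 0.22 and 1.05 ± 0.15. Chrm4, a muscarinic acetylcholine receptor, fell most (-3.35 ± 0.56), followed by neuroglobin (Ngb, -2.33 ± 0.48) and Asb4 (-1.83 ± 0.32). The peptide genes Pdyn (prodynorphin, -1.58 ± 0.29) and Grp (gastrin-releasing peptide, -1.52 ± 0.29) fell, as did Ddc, which makes dopamine and serotonin (-1.37 ± 0.28), Dnah1 (-1.38 ± 0.25) and Rps27rt (-1.30 ± 0.22). In all, edgeR called 132 of 13342 genes, 30 higher and 102 lower, and 2110 had an unadjusted p under 0.05; adjusted p for the named genes lay between 0.0377 and 0.0483.

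Of 15 cholinergic and monoaminergic neuron markers, 1 fell with NTG over all genes (Ddc) and 13 passed when adjusted over the list alone. The median was -1.53 (camera adjusted p = 5.27e-13, adjusted p = 0.220 with an estimated correlation). Slc6a4, the serotonin transporter, was at -2.96 ± 0.71 and did not pass. The mean log2 score of these markers was 3.68 ± 0.329 in VEH and 2.17 ± 0.874 in NTG (SD, n = 4 each, exact permutation p = 0.0571), and NTG 3, at 3.34, lay above the other NTG libraries. Of 39 migraine and pain peptides and receptors, 3 fell, namely Pdyn, Grp and the orexin receptor Hcrtr1 (-1.09 ± 0.21), and 10 passed adjusted over the list alone (median -0.27, camera adjusted p = 7.37e-06, adjusted p = 0.220 with an estimated correlation). The 5 caudal Hox genes had a median of 1.78 and none passed over all genes, with all 5 passing adjusted over the list alone (camera adjusted p = 1.69e-05, adjusted p = 0.220 with an estimated correlation). None of 19 oligodendrocyte markers passed over all genes, and 17 did adjusted over the list alone (median 0.37, camera adjusted p = 1.58e-08, adjusted p = 0.579 with an estimated correlation). The count of 132 fell to 0 without NTG 1, NTG 2, NTG 4, VEH 3 or VEH 4 and to 1 without VEH 1, and rose to 535 without NTG 3 and 652 without VEH 2. It was 4 with the replicate number as a block, 75 with median scaling, 2 in a fit of these 2 groups alone, 668 with DESeq2 and 994 with sample weights in limma.

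NTGKA against VEH in the VN gave more calls. The relaxin-family peptide gene Rln3 fell by 7.43 ± 1.74 on the log2 scale, from 251 ± 41.1 FPKM in VEH (SD, n = 4) to 1.29 ± 1.19 in NTGKA (n = 3), with NTG at 61.6 ± 117 (n = 4). Serotonin genes fell, namely Tph2, the rate-limiting enzyme of neuronal serotonin synthesis (-3.89 ± 0.85), and Slc6a4 (-3.55 ± 0.82), as did the nicotinic receptor subunit Chrna5 (-3.31 ± 0.77), Slc10a4, a protein of cholinergic and monoaminergic vesicles (-3.39 ± 0.72), Dmrtb1 (-3.83 ± 0.68) and Uts2b (-3.13 ± 0.68). Urotensin 2 (Uts2), with 0 counts in NTGKA, was at least 82.2-fold lower, and at least 47.6-fold without NTGKA 2. Dmbx1 rose by 3.33 ± 0.65, Hoxb3 by 2.55 ± 0.44, Pax8 by 2.50 ± 0.39, Hoxa4 by 2.38 ± 0.48, and the retinoic acid binding protein Crabp1 by 1.94 ± 0.43. Plin4 (1.85 ± 0.41), Serpinb1b (1.80 ± 0.28) and Lamp5 (1.80 ± 0.30) rose too. In all, edgeR called 403 of 13342 genes, 141 higher and 262 lower, with 2285 at an unadjusted p under 0.05 and adjusted p for the named genes of 0.0161 to 0.0386.

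Of the 15 cholinergic and monoaminergic markers, 9 fell with NTGKA and 14 passed adjusted over the list alone, with a median of -2.62 (camera adjusted p = 2.20e-20, adjusted p = 0.147 with an estimated correlation). Chat, which makes acetylcholine, fell by 2.62 ± 0.47, Ddc by 1.82 ± 0.32, Maoa by 0.98 ± 0.19 and the choline transporter Slc5a7 by 2.53 ± 0.49. Their mean score was 1.68 ± 0.392 in NTGKA (n = 3, exact permutation p = 0.0286 against VEH, 0.162 after adjustment over the cell types). Microglia and astrocyte markers had the same p-values, with log2 differences of -0.22 and -0.081. Of 5 caudal Hox genes 3 rose, Hoxb4 (3.78 ± 0.68), Hoxa4 and Hoxc5 (2.76 ± 0.69), with 4 passing adjusted over the list alone (camera adjusted p = 4.98e-07, adjusted p = 0.147 with an estimated correlation). Of 4 rostral Hox genes 2 rose, Hoxb3 and Hoxa2 (1.55 ± 0.28), with 3 passing adjusted over the list alone (camera adjusted p = 5.48e-06, adjusted p = 0.147 with an estimated correlation). Of the 39 peptides and receptors 6 fell and 15 passed adjusted over the list alone, among them Pdyn (-2.11 ± 0.33), Hcrtr1 (-1.30 ± 0.23), Adcyap1, which encodes the migraine-related peptide PACAP (-0.81 ± 0.16), and Grp (-1.54 ± 0.32). That list had a camera adjusted p of 0.000297, and adjusted p = 0.393 with an estimated correlation. Among 22 immediate early genes, which report neuronal activity, 3 fell, Nr4a3 (-2.27 ± 0.45), Nr4a2 (-1.37 ± 0.29) and Egr1 (-0.48 ± 0.11), 5 passed adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.102). The count of 403 fell to 0 without VEH 3, NTGKA 2 or NTGKA 3, to 1 without VEH 1, to 76 without NTGKA 1 and to 160 without VEH 4, and rose to 778 without VEH 2. It was 123 with the replicate number as a block, 906 with DESeq2 and 1853 with sample weights in limma.

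Ion channels in the VN changed in both directions. With NTG, 3 of 255 rose and 4 fell by edgeR, and 37 passed adjusted over the list alone (15 higher, 22 lower). The sodium channel subunit Scn4b rose (0.78 ± 0.14) and Scn3b fell (-0.89 ± 0.17). The potassium channel genes Kcna2 (0.46 ± 0.09) and Kcnab2 (0.51 ± 0.10) rose and Kcns2 (-0.91 ± 0.19) fell, together with the calcium channel subunit Cacnb3 (-0.82 ± 0.16) and the glycine receptor subunit Glra2 (-1.02 ± 0.20). With NTGKA, 11 rose and 20 fell, and 62 passed adjusted over the list alone (18 higher, 44 lower). The GABA-A receptor subunits Gabre (-2.36 ± 0.43) and Gabrq (-2.41 ± 0.46) fell, with Glra2 (-1.25 ± 0.23), Cacna2d1 (-1.21 ± 0.22) and Scn3b (-0.96 ± 0.19), while Kcnab3 (0.80 ± 0.12), Scn4b (0.75 ± 0.15) and Kcna2 (0.50 ± 0.10) rose. Of the 34 calcium channels 1 rose and 7 fell with NTGKA, and 14 passed adjusted over the list alone (camera adjusted p = 3.91e-05, adjusted p = 0.393 with an estimated correlation). The NTG count of 7 was 36 without NTG 3, 35 without VEH 2 and 0 without any one of the other 6 libraries, and the NTGKA count of 31 was 0 without VEH 1, VEH 3, NTGKA 2 or NTGKA 3, 11 without VEH 4 and 6 without NTGKA 1. Adjusted over the list alone, the NTG count was 7 without NTG 1, 8 without VEH 1 or VEH 3, 71 without NTG 3 and 74 without VEH 2, and the NTGKA count was 37 without VEH 1, 38 without VEH 3, 31 without NTGKA 2 and 39 without NTGKA 3.

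**Figure D2:**
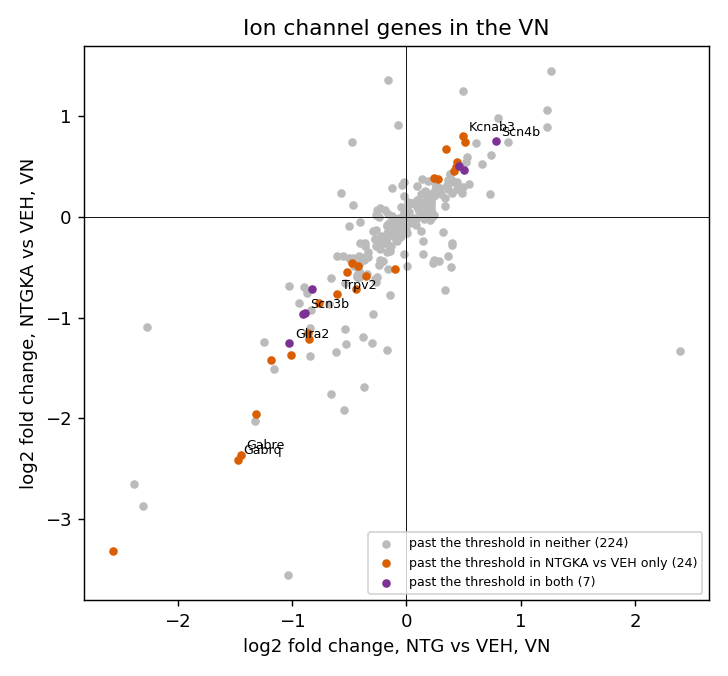
Log2 fold changes of 255 ion channel genes in the VN, NTG against VEH on the horizontal axis and NTGKA against VEH on the vertical axis; each point is a gene, coloured by whether edgeR called it. Of the genes, 7 passed in both comparisons, 24 with NTGKA only, 0 with NTG only and 224 in neither; both axes share the VEH libraries.

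NTGKA against NTG in the VN asked what kainic acid adds. edgeR called 0 of 13342 genes, with 433 at an unadjusted p under 0.05 where chance would give 667.1, and DESeq2 called 1. The genes with the smallest p, none of which passed (edgeR adjusted p = 0.999), were Gbx2 (1.53 ± 0.32), Osgepl1, Atp6v1g2, Lcn2 (4.46 ± 1.20, and 0.55 ± 1.02 without NTGKA 1) and Dqx1 on the higher side and Ripk1 (-1.08 ± 0.21), Cers3, Prkg1, Pde3a and Pafah2 on the lower. The channels with the smallest p were Cacna1i (-0.41 ± 0.13), Kcne2 and Itpr1. Trpv2 differed by -0.16 ± 0.18 (exact permutation p = 0.686). Against VEH, the NTG and NTGKA calls shared 27 higher and 85 lower genes, where independent lists would share 0.317 and 2.0. Their fold changes over genes had r = 0.714 and a covariance of 0.155. Unchanged groups simulated against the same controls gave a mean r of 0.457 and a covariance of 0.0409. With the controls halved, so that the comparisons shared no VEH library, the observed r was 0.375 to 0.467 and the covariance 0.0896 to 0.105. The simulated values come from shared controls and are not the reference for the halved ones. In the Sp5C, halved controls gave an r of -0.162 to 0.0584. Genes are not independent replicates in these correlations.

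In the Sp5C, no gene passed in any treatment comparison. For NTG against VEH, edgeR called 0 of 13356 genes, with 339 at an unadjusted p under 0.05, and DESeq2 called 0. Chance would give 667.8 such genes in each Sp5C comparison, so 339 is no excess. The 0 calls do not show that nothing changed. The genes with the smallest p were Ldah (0.25 ± 0.07), Tbx1 (1.01 ± 0.28), Plin4 (1.30 ± 0.36), Prrx1 and Fgf1 on the higher side, and Pcif1 (-0.30 ± 0.07), Abcc12, the kinase gene Sgk1 (-0.85 ± 0.22), Nanp and Rgs12 on the lower (edgeR adjusted p = 0.997). For NTGKA against VEH, edgeR called 0, with 285 at an unadjusted p under 0.05, DESeq2 called 0 and sample weights in limma gave 1. The clock gene Per1 (-0.73 ± 0.15), Thumpd2, Sgk1 (-1.07 ± 0.24), Klf2 and Cyren were lowest by p, and Gm49322 (1.10 ± 0.24), Lrg1 (2.14 ± 0.50, and 1.23 ± 0.46 without NTGKA 1), Stac, Podxl and Plin4 (1.52 ± 0.38) highest. Plin4 was 2.97 FPKM in Sp5C NTGKA 1, and 1.14 and 0.764 in NTGKA 2 and 3, against 0.552 ± 0.0107 in VEH (SD, n = 4). For NTGKA against NTG, edgeR called 0, with 660 at an unadjusted p under 0.05, and DESeq2 called 1. Calca, which encodes the migraine peptide CGRP, was at 1.23 ± 0.30, 5.06 ± 0.961 FPKM in NTGKA (SD, n = 3) and 2.05 ± 0.566 in NTG (n = 4), and did not pass (edgeR adjusted p = 0.840); Gm49322 (1.34 ± 0.24) and Fads2 (-0.45 ± 0.12) were also among those with the smallest p. No ion channel passed, and those with the smallest p were Lrrc8c, Scn7a and Tpcn1 for NTG, Gabre, P2rx5 and Ttyh1 for NTGKA, and Kcnn2, Orai1 and Kcnj10 between them. Of the 47 lists, none passed with an estimated correlation in these comparisons, the smallest adjusted p being 0.626, 0.505 and 0.617 (9, 10 and 10 passed with the preset one). Without Sp5C NTGKA 3, both NTGKA comparisons called 1 gene.

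Between the regions of vehicle mice, differences were large. Hox genes, which mark position along the hindbrain and spinal cord, were higher in the Sp5C, with all 12 caudal members passing (median 6.90, camera adjusted p = 2.77e-36, adjusted p = 0.00185 with an estimated correlation). Hoxb5 was higher by 9.09 ± 0.63, Hoxb6 by 9.24 ± 0.82, Hoxb4 by 6.91 ± 0.59 and Hoxa5 by 6.89 ± 0.50. Hoxb8, Hoxb7 and Hoxc6 had 0 counts in the VN and were at least 2077-fold, 338-fold and 134-fold higher, and 514-fold, 108-fold and 79.1-fold without Sp5C VEH 4. Of the 17 Hox genes that reached 0.5 FPKM, 13 had all Sp5C libraries above all VN libraries and 0 the reverse, which fits the title and tissue labels. Of 4 rostral Hox genes 3 were higher (median 1.97, adjusted p = 0.0179 with an estimated correlation). The VN had more Rln3 (-9.13 ± 1.42), noradrenergic Slc6a2 (-6.77 ± 0.89) and Dbh (-6.42 ± 0.95), Slc10a4 (-5.85 ± 0.67), Uts2b (-5.53 ± 1.26) and the nicotinic subunits Chrnb3 (-5.91 ± 1.12) and Chrna6 (-5.76 ± 1.02). Pax7 had 2 counts in the Sp5C and 1240 in the VN, a ratio of 637 (95% interval 176 to 5263, from counting error alone), and without Sp5C VEH 2, which leaves 0 counts in the Sp5C, at least 320. In all, edgeR called 2216 of 13650 genes, 1039 higher in the Sp5C and 1177 higher in the VN, with 4210 at an unadjusted p under 0.05.

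All 15 cholinergic and monoaminergic markers were lower in the Sp5C adjusted over the list alone, and 14 over all genes (median -3.67, adjusted p = 0.0140 with an estimated correlation). Of 17 circadian clock genes 5 were higher, led by Hlf (1.30 ± 0.13) and Bhlhe40 (0.68 ± 0.11), and the list passed (adjusted p = 0.00234 with an estimated correlation). Gfap, the astrocyte filament gene, was 177 ± 50.7 FPKM in the Sp5C and 35.2 ± 3.71 in the VN (SD, n = 4 each), a difference of 2.29 ± 0.20. Of 16 choroid plexus markers 11 were higher, with adjusted p = 0.546 with an estimated correlation, and Kl (4.33 ± 1.04) was first by p. Their mean log2 levels in Sp5C VEH 1 to 4 were 0.71, 1.20, 2.79 and 3.52, and the count of 11 was 0 without both Sp5C VEH 3 and Sp5C VEH 4, 5 without Sp5C VEH 3, 4 without Sp5C VEH 4, and 5, 6, 3 and 4 without VN VEH 1, 2, 3 and 4. Myoc (7.10 ± 0.69) and Prr32 (7.11 ± 1.77) were also higher. Of 54 cytosolic ribosomal protein genes 30 were lower, led by Rpl10a (-0.52 ± 0.11), with adjusted p = 0.443 with an estimated correlation, and 17 without VN VEH 3, 3 without VN VEH 4, 8 without Sp5C VEH 1 and 8 without Sp5C VEH 3. Trpv2 was lower in the Sp5C by -1.08 ± 0.18 (edgeR adjusted p = 0.000299, exact permutation p = 0.0286). With NTGKA its levels were closer, 3.82 ± 0.0914 FPKM in the VN and 3.44 ± 0.208 in the Sp5C (SD, n = 3 each). Of 264 ion channels 50 were higher and 34 lower, and 100 passed adjusted over the list alone. Gabre (-3.61 ± 0.42) and Gabrq (-3.08 ± 0.43) were lower, and Kcnab3 (0.92 ± 0.11), Kcnt1 (0.55 ± 0.07), Gabra5 (1.14 ± 0.16) and Kcnj3 (0.99 ± 0.14) higher. The count of 2216 was 1438 without VN VEH 3, 1272 without VN VEH 4, 1340 without Sp5C VEH 1 and 1335 without Sp5C VEH 3, and 4509 with sample weights in limma.

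**Figure D3:**
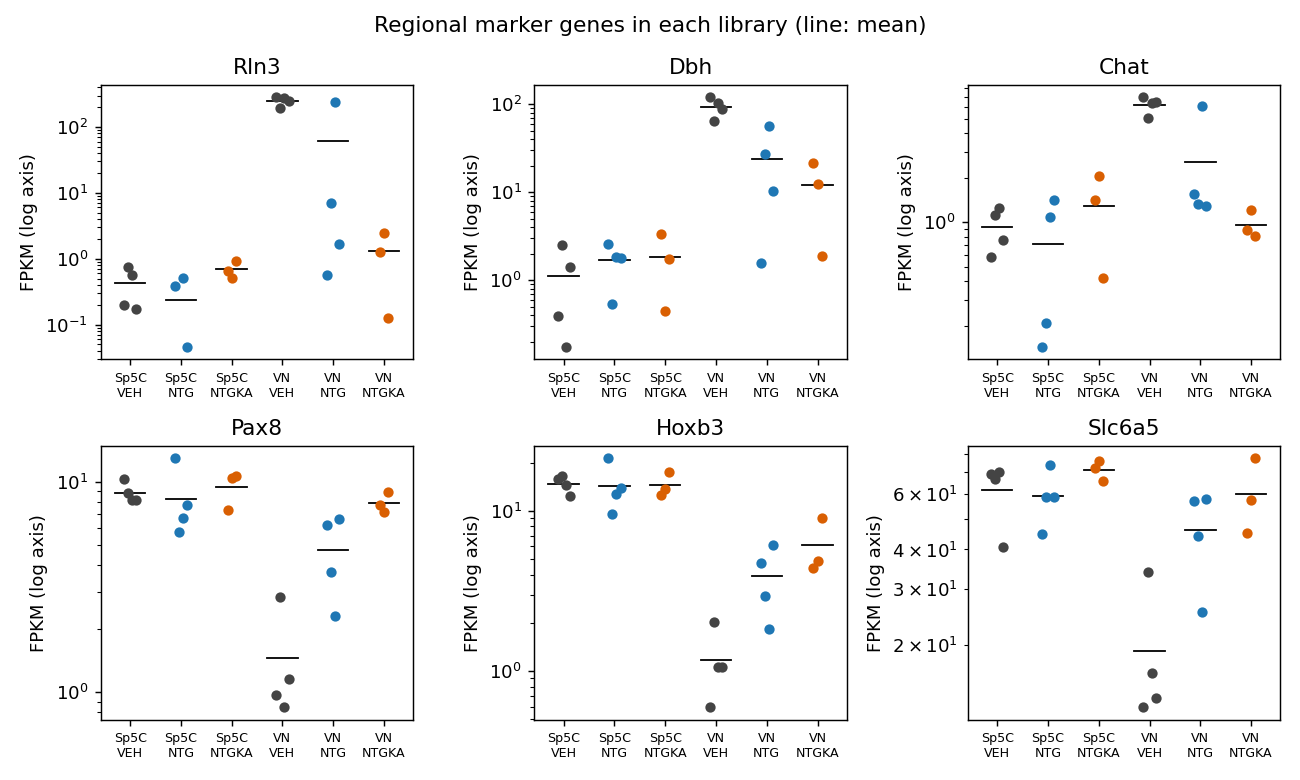
Levels (FPKM, log axis) of Rln3, Dbh, Chat, Pax8, Hoxb3 and Slc6a5 in each library by region and treatment; each point is a library, lines are means, and 1 Sp5C NTG library with 0 FPKM of Rln3 cannot be drawn on the log axis. Rln3 ranges from 193 to 282 FPKM in the 4 VN VEH libraries and from 0.126 to 2.50 in the 3 VN NTGKA libraries, while 1 VN NTG library stands at 237.

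Whether the treatment response differed between regions was tested as an interaction. For NTG, edgeR called 0 of 13650 genes, with 1148 at an unadjusted p under 0.05 and a smallest adjusted p of 0.180, and DESeq2 called 27. For NTGKA, edgeR called 0, with 1381 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0640, and DESeq2 called 148. The genes with the smallest p for NTGKA were Vat1 (1.37 ± 0.24), Gabre (3.34 ± 0.60), Gpr101, Zmym3 and Glra2 (1.56 ± 0.31), with a response higher in the Sp5C, and Sptssb (-1.12 ± 0.20), Lamp5 (-1.80 ± 0.34), Kcnab3 (-0.88 ± 0.17), Tshz3 and Crtac1, with a lower one. For NTG they were Rimbp2 (1.23 ± 0.26), Sprn, Brinp2, Sfxn1 and Epb41l4a, and Crtac1 (-0.72 ± 0.13), Sptssb, Lamp5, Hopx and Foxb2, with the channels Cacng5, Kcns2 and Gabre. Trpv2 differed by 0.53 ± 0.26 for NTG (edgeR adjusted p = 0.592) and 0.84 ± 0.28 for NTGKA (edgeR adjusted p = 0.237). The cholinergic and monoaminergic list passed for NTGKA (median 2.84, camera adjusted p = 0.0424 with an estimated correlation). Of its members, 0 were past the threshold over all genes and 11 adjusted over the list alone. In VEH their mean log2 score was 0.990 ± 0.191 in the Sp5C and 3.68 ± 0.329 in the VN (SD, n = 4 each). A fall as large as in the VN could hardly be seen from the low Sp5C level. Without VN NTG 3, VN VEH 2, VN VEH 1 or Sp5C VEH 4 the NTG count was 50, 16, 1 and 1, and without VN VEH 2 or VN VEH 1 the NTGKA count was 111 and 1.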

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

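The tests of dissection position, of Trpv2 inside the groups, of vehicle libraries alone, of marker-score adjustment, of exchanged labels, of Lcn2 and Lrg1 in the other NTGKA libraries and of the ratio to the number expected were chosen only after the result was seen; the tests of depth, of the Sp5C, of library pairs and of other splits were set before theirs.

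The VN differences between treated and VEH libraries went with markers of neighbouring cell groups. Among called genes outside the marker list, 96.9% (NTG) and 98.2% (NTGKA) followed the cholinergic and monoaminergic score inside the groups, where the dose does not vary. They did so with the sign of the group difference (exact permutation p = 0.0208 and 0.000579 over 3456 rearrangements). Pieces cut at slightly different positions would give this. A response to treatment that varied between the libraries of a group would give it too, so the treated groups cannot tell these apart. Inside VEH alone, which had no treatment, the shares were 96.9% and 90.9% (exact permutation p = 0.167 and 0.0833). Over all groups without VEH 2 and NTG 3 the shares were 70.2% and 74.1% (exact permutation p = 0.139 and 0.0278 over 216 rearrangements). With the score as a covariate the calls went from 132 and 403 to 0 and 0, the median absolute log2 change of the called genes from 0.74 to 0.34 and from 0.72 to 0.25, and their median SE from 0.15 to 0.19 and to 0.23, so smaller changes and wider errors ended the calls. The score was 3.21 to 3.98 in the VEH libraries and 1.23 to 1.96 in the NTGKA libraries, without overlap. A treatment effect on these markers would shrink under the adjustment as well, so the covariate cannot tell it from position. Depth is argued against, since thinning to the smallest total left at least 128 and 373 calls. A treatment effect remains open: 67.4% and 42.7% of the called genes moved the same way in the Sp5C (exact permutation p = 0.343 and 0.686), which decides nothing. A loss of these neurons with treatment would lower the same markers, but would hardly raise other genes. With NTGKA 141 of the 403 called genes rose. Mean log2 levels of rostral Hox genes were 0.805 to 1.07 in VN NTGKA and -0.167 to 0.34 in VEH. Slc6a5 went from 19.1 ± 9.96 FPKM in VEH (SD, n = 4) to 59.97 ± 16.4 in NTGKA (n = 3). These values argue against loss alone for the genes that rose with NTGKA. For NTG the Hox levels overlapped those of VEH (0.255 in NTG 3), so loss stays open there.

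Trpv2 in the VN followed the marker score inside the groups (r = 0.845, exact permutation p = 0.0208, and rho = 0.618, exact permutation p = 0.0842). The r was 0.460 without NTG 1 and NTG 3, the 2 libraries whose score lay farthest out once group means were taken off. Those means still included both libraries. The relation therefore rests in part on NTG 1 and NTG 3, and the label of NTG 3 is in doubt (below). With the score as a covariate its change went from -0.61 ± 0.16 to -0.09 ± 0.19 for NTG and from -0.77 ± 0.18 to -0.04 ± 0.24 for NTGKA. The lower Trpv2 of treated libraries may follow the position of the dissected piece, as a hypothesis. A treatment effect was not excluded, since the score is itself lower in treated libraries and the adjustment would shrink such an effect too. A response that varied between libraries would also give the relation inside the treated groups. The interaction of treatment and region for Trpv2 was 0.53 for NTG (edgeR p = 0.0490, adjusted p = 0.592 over all genes) and 0.84 for NTGKA (edgeR p = 0.00601, adjusted p = 0.237 over all genes), and that of the marker list for NTGKA was 2.84 (adjusted p = 0.0424 with an estimated correlation).

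Lcn2 and Lrg1, which rise in inflammation, were high in replicate 1 of NTGKA in both regions, with Lcn2 at 25.7 FPKM in the VN and 22.3 in the Sp5C. An effect shared by the NTGKA animals remains open, since of the 4 other NTGKA libraries 1 had Lcn2 and 3 had Lrg1 above the highest VEH or NTG library of their region, 4 of 8 values. Both libraries of replicate 1 shared 77 genes at least 2-fold above the other NTGKA libraries, where the highest other of the 9 pairings had 26; these include the neutrophil genes S100a8, S100a9 and Ngp, chosen after their values were seen. Mean log2 levels of peripheral leukocyte markers were 0.138 in VN NTGKA 1, against -0.363 and -0.495 in NTGKA 2 and 3, and 0.494 in Sp5C NTGKA 1, against -0.109 and -0.375. Whether leukocytes in the tissue or in its blood account for the pattern was not tested. Relative to the number expected the ratio was 7.89, with 7.77 for the pair of replicates 2 and 9.24 for that of replicates 3, against 3.33 to 7.23 for the 6 pairs with different numbers. All 3 same-numbered pairs are above the others, which goes with shared animals, but the margin is small, so a single animal behind both libraries could not be settled and may account for it.

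Other splits of the libraries were counted for each comparison. For the VN, 2 of 35 splits gave as many genes as NTG against VEH (132, highest other 348) and 2 of 35 as many as NTGKA against VEH (403, highest other 567), so chance cannot be excluded. The split with 348 sets NTG 1, NTG 2, NTG 4 and VEH 2 against the rest, and that with 567 sets VEH 1, VEH 3 and VEH 4 against the rest, which points to a structure of the samples. The first of these exchanges VEH 2 and NTG 3. On the 200 genes with the smallest p without both, where the other NTG libraries have a mean of 0 and the other VEH libraries a mean of 1, VEH 2 stood at 0.493 and NTG 3 at 0.540 (medians), between the other NTG libraries (up to 0.244) and the other VEH libraries (from 0.845). Exchanged labels of these 2 libraries therefore remain open, and if they were exchanged the VN counts of 132 and 403 would not be those of the treatments. For the comparisons with 0 calls every split gives at least as many, 35 of 35 (highest other 1 for NTG and 1 for NTGKA against VEH and 4 for NTGKA against NTG in the Sp5C, 1 for NTGKA against NTG in the VN), and 60 of 60 drawn for both interactions (highest other 18 and 40), so the splits decide nothing there. For the regions, 1 of 35 splits gave as many as 2216 (highest other 189), which argues against chance. That 1 is the real split, so 1 of 35 is the smallest share this test can give.

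Single libraries stood apart from their group in 15 of 312 groups of 4 libraries tested, where chance gives about 1 in 20. In VN NTG 3, Rln3 was 237 FPKM, Tph2 9.74, Chat 6.06 and Glra2 9.12, all above the other NTG libraries. In VN VEH 2, Pax8 was 2.84, Pax2 2.99 and Lamp5 100.2 FPKM, above the other VEH libraries. Mean log2 marker levels were 3.86 for choroid plexus in Sp5C NTG 1, 3.06 for red blood cells and -0.38 for peripheral leukocytes in VN VEH 4, and 2.41 for apoptosis and injury genes in Sp5C VEH 4, all above the rest of the group. Sgk1 was 28.1 FPKM in Sp5C NTG 3 and Lrg1 0.918 in VN NTG 4, both highest, while Slc6a5 was 40.8 in Sp5C VEH 4 and Pdyn 1.67 in Sp5C NTG 2, both lowest.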

How the results depend on the processing

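Limma on log2(FPKM + 0.5), library sizes implied by count and FPKM, and leaving out Sp5C NTG 1 and Sp5C VEH 4 were chosen after seeing the data. Over the single genes reported and the lists, 13007 values kept their direction and side of the threshold, 566 passed only under the alternative, 1136 no longer passed and 13 changed direction. The cause was not tested for any change below unless the number of libraries or genes in the fit accounts for it. Replicate numbers were not taken as pairs, since same-numbered libraries of the 2 regions correlated at -0.0364 to 0.134, with 3 of 11 above 0.1. Their mean was 0.0441, against -0.0164 for other numbers (permutation p = 0.0292 one-sided and 0.0674 two-sided, chosen after seeing the data), and 6 of 11 Sp5C and 5 of 11 VN libraries correlated best with their own number, so shared animals behind some numbers remain open.

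Gene counts for NTG against VEH in the VN (132, 30 higher) were 223 (29 higher, 194 lower) with a pseudocount of 0.1, 252 (30, 222) with 1, 201 (56, 145) with no filter, 75 (13, 62) with median scaling, 4 (3, 1) with the replicate block, 994 (201, 793) with sample weights, 668 (283, 385) with DESeq2, 244 (30, 214) with limma on FPKM, 208 (28, 180) with library sizes from FPKM, 224 (86, 138) over all 22 libraries and 2 (0, 2) over these groups alone; without single libraries 0 to 652. For NTGKA against VEH (403) they were 123 (38, 85) with the replicate block, 1853 (578, 1275) with sample weights and 906 (349, 557) with DESeq2; library sizes from FPKM gave 407 (83, 324), a lower share of higher genes than 141 of 403; without single libraries 0 to 778. Sample weights gave 4509 (2340, 2169) for the regions (2216), and single libraries 1272 to 2412. Counts of 0 became 1 for Sp5C NTGKA against VEH with sample weights, and 1 with DESeq2 for NTGKA against NTG in the Sp5C and in the VN; without single libraries both Sp5C NTGKA comparisons gave 0 to 1.

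The NTG interaction (0) gave 41 with sample weights and 27 with DESeq2, and 0 to 50 without single libraries. The NTGKA interaction (0) gave 31 with a pseudocount of 1, 30 with quantile normalization, 28 with median scaling, 782 with sample weights, 148 with DESeq2, 27 with limma on FPKM, 3 with library sizes from FPKM and 68 with same-numbered libraries as a random replicate block, and 0 to 111 without single libraries.

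Ion channel counts for NTG in the VN (7) were 15 and 19 with pseudocounts of 0.1 and 1, 14 with quantile normalization, 1 with the replicate block and 17 with limma on FPKM, and without single libraries 0 to 36 (adjusted over the list alone 7 to 74). For NTGKA (31) the replicate block gave 9, and single libraries 0 to 44 (adjusted over the list alone 31 to 81). For the NTG interaction, single libraries gave 0 to 9; adjusted over the list alone (10) the count was 16, 18, 16 and 17 with pseudocounts of 0.1 and 1, median scaling and limma on FPKM, and 0 to 27 without single libraries. For the NTGKA interaction (0) it was 6, 6, 5 and 5 with a pseudocount of 1, quantile normalization, median scaling and limma on FPKM, and 0 to 12 without single libraries; adjusted over the list alone (22) it was 34 with the replicate block and 9 to 41 without single libraries.

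Trpv2 for NTGKA in the VN (-0.77) no longer passed with a pseudocount of 0.1 (-0.76), quantile normalization (-0.62), median scaling (-0.66) or the replicate block (-0.78), and was -0.84 to -0.69 without single libraries. For NTG in the VN single libraries gave -0.78 to -0.48. Its change, which did not pass, turned sign for Sp5C NTG (-0.23 to 0.087), Sp5C NTGKA (-0.019 to 0.23) and VN NTGKA against NTG (-0.29 to 0.0081) without single libraries. With an estimated correlation, the lists passing went from 9, 10, 10, 12, 15, 7 and 14 to 0 in the 6 treatment comparisons and the NTG interaction, from 18 to 4 for the regions and from 9 to 1 for the NTGKA interaction.

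Members of lists that did not pass turned sign as follows. For Sp5C NTG, sample weights gave -0.046 for Shank1, and leaving out Sp5C NTG 1 and Sp5C VEH 4 gave -0.031 for Dlg2. For Sp5C NTGKA against NTG that fit gave 0.094 for Trpv4, 0.95 for Sostdc1 and 0.14 for Enpp2, sample weights gave 0.11 for Sostdc1, and single libraries gave -2.16 to 0.094, -3.88 to 0.95 and -1.80 to 0.14. For VN NTG single libraries gave -0.00329 to 0.11 for Bpgm and -0.37 to 0.23 for Hbb-bs. Depth may limit low genes such as Chrm4, at 1.36 FPKM in VN VEH, which was not tested gene by gene.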

Other observations

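The test of treated against VEH libraries over both regions, and that without replicate 1 of NTGKA, were chosen only after the results were seen; the test of the glucocorticoid list was set before its result.

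Inside the VN, genes of inhibitory neurons did not move together with treatment. Slc6a5, the glycine transporter of inhibitory neurons, rose with NTGKA by 1.68 ± 0.33 (edgeR adjusted p = 0.0215), from 19.1 ± 9.96 FPKM in VEH (SD, n = 4) to 59.97 ± 16.4 in NTGKA (n = 3), and Pax2 rose by 1.66 ± 0.31, while Gata3 fell by 1.10 ± 0.28. Of the 11 GABAergic and glycinergic markers, 2 rose, 1 fell and 7 passed adjusted over the list alone (adjusted p = 0.813 with an estimated correlation). Among pan-neuronal genes, Gap43, a growth cone protein, fell by 1.04 ± 0.16 and Syt1 by 1.13 ± 0.24, and Snap25 rose by 0.50 ± 0.09. Calca, chosen after its values were seen, was 34.6 ± 7.26 FPKM in VN VEH (n = 4) and 4.46 ± 2.83 in NTGKA (n = 3).

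In a fit of treated against VEH libraries over both regions, edgeR called 56 of 13650 genes, 26 higher and 30 lower. Of all genes tested, 1657 had an unadjusted p under 0.05. The fit takes the 22 libraries as independent, so its p-values may be too small if the regions share animals. It averages the regions, so a change in the VN alone can pass. Lamp5, Pax8, Hoxb3 and Slc6a5, which rose with NTGKA in the VN, were among the calls. Lamp5 in the Sp5C was 161 ± 9.80 FPKM in VEH, 147 ± 11.6 in NTG and 164 ± 8.26 in NTGKA (SD). Sgk1 (-0.87 ± 0.13, edgeR adjusted p = 0.0167) and Per1 (-0.55 ± 0.10, edgeR adjusted p = 0.0296) fell and Plin4 (1.63 ± 0.27, edgeR adjusted p = 0.0286) rose. Of 60 splits drawn, 3 gave as many genes (highest other 224), so chance cannot be excluded. Less glucocorticoid signalling in treated animals may lower Sgk1 and Per1, as a hypothesis, but would also lower Plin4 if that is a target. The other 14 genes of the glucocorticoid list had a median of 0.08, with 0 past the threshold (camera p = 0.396 with an estimated correlation), so the hypothesis could not be settled. Replicate 1 of NTGKA had the highest mean log2 level of the whole list in both regions (3.04 in the VN and 3.27 in the Sp5C, up to 2.75 and 2.84 in the other libraries). Without both, the 14 genes had a median of 0.015 (camera p = 0.789 with an estimated correlation), edgeR called 9 genes, and Sgk1 (-0.97), Per1 (-0.60) and Plin4 (1.36) passed. The count of 56 was 0 without VN VEH 3 or Sp5C VEH 3, 1 without VN VEH 4, Sp5C VEH 1 or Sp5C VEH 2, 2 without VN NTG 1, VN VEH 1 or Sp5C NTGKA 2, 3 without VN NTGKA 3 or Sp5C NTGKA 1, 6 without VN NTG 4 or Sp5C VEH 4, 11 without VN NTGKA 2, 18 without Sp5C NTG 3, 32 without VN NTG 2, 114 without Sp5C NTG 4, 197 without Sp5C NTG 1, 255 without VN NTG 3 and 353 without VN VEH 2. Sgk1 did not pass without VN VEH 3 or Sp5C VEH 3, Plin4 without these, VN VEH 1, VN VEH 4, Sp5C VEH 1 or Sp5C VEH 2, and Per1 without any of these 6, VN NTG 1, VN NTGKA 3 or Sp5C NTGKA 2.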
